A study of Homo sapiens with 4 samples.

How the data were processed

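RNA from SK-CO-1 cells was compared on 4 Agilent dual-channel expression arrays. Per the labels, each Cy5 sample came from cells given 50 nM β-catenin siRNA and 50 nM of TNFR1 siRNA5 or siRNA6, each Cy3 sample from cells given 50 nM β-catenin siRNA and 50 nM control RNA, and 200 ng of RNA was labelled. Samples were grouped by TNFR1 siRNA, with 2 arrays per siRNA, 1 in each of 2 numbered experiments. All 4 arrays lay on 1 slide, and no array had swapped dyes.

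Per the file headers, the arrays were read with Agilent Feature Extraction 11.5.1, and the mean spot and median local background brightness of each channel are raw intensity values. The processed signals are also intensity values, which per the file headers were detrended, background-subtracted and dye-normalised with LOWESS inside each array, with surrogate values for dim spots. The log ratio of each spot is a log10 ratio of the processed Cy5 over Cy3 signals, per the file headers, and its p-value comes from Feature Extraction's error model for 1 array, per the file headers. That p-value was under 0.01 for 800, 1289, 275 and 1433 spots on the arrays siRNA5 experiment 1, siRNA6 experiment 1, siRNA5 experiment 2 and siRNA6 experiment 2, in that order. The deposited series table holds log2 ratios. Their scale was checked against the processed signals over 50739 matched probes, with a slope of 3.32 per log10 unit on each array and r over 0.9997. The deposited log2 ratios had medians of -0.12, 0.07, -0.03 and 0.34 over all matched probes on the 4 arrays in the same order, and of 0.0144, 0, -0.0144 and 0 over the probes tested here.

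Each array held 62976 spots, 58717 of them not controls. In the same order, 50.7, 54.2, 48.7 and 48.1% of spots were well above background in Cy3, and 53.6, 53.5, 49.0 and 44.6% in Cy5. The arrays had 0 saturated spots in either channel, and 435, 423, 571 and 622 spots were left out for Feature Extraction's outlier flags. The observed log ratios of the spike-in controls rose with the designed ones with slopes of 0.901, 0.928, 0.918 and 0.919. These shares limit how many dim transcripts can be measured, and 2 arrays per siRNA limit the precision.

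Ratios were computed from the raw brightness in limma 3.58.1 (R 4.3.3, with the package data.table at version 1.17.8), with normexp background correction at an offset of 50 and loess within arrays (span 0.3, 4 iterations, control spots at weight 0). Spots of a probe were averaged. Of 50599 probes, 25373 that were well above background in at least 1 channel on at least 2 arrays were kept, and 24 were dropped because flags left no value. Gene names came from the RefSeq gene table for the assembly GRCh38.p14 by accession for 29033 probes and from the array files for the other 21566, and no coordinate of that build was used. Coordinates are those of the array files, on hg19. The brightest probe stood for each gene, which left 18875 genes, 14455 of them under a current symbol. Of these, 4437 had several kept probes. A gene whose channel was not well above background on any array was given as a bound against the background floor.

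A model with 1 mean per siRNA (2 residual degrees of freedom) was fitted to all genes with limma's lmFit and eBayes, and p-values were adjusted with Benjamini-Hochberg over all genes of a comparison. The comparisons, chosen before the data were examined together with the gene lists, the rule for named genes and the alternative settings, were the mean of both siRNAs against 0, each siRNA against 0, and siRNA5 minus siRNA6. All tests were two-sided. Because the numbers of the experiments could pair arrays, the log2 ratio of experiment 1 minus experiment 2 was compared between the siRNAs across genes. Its r was -0.146 (rho -0.147), so the fit without pairs was kept as planned and the experiment was used as a block in an alternative.

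The 26 gene lists covered the TNFR1 complex, other TNF-family members, TNF and NF-κB targets, Wnt targets, the BCL2 family and caspases, death-associated kinases and autophagy, interferon-stimulated genes, antigen presentation, cell cycle, p53 targets, the unfolded protein response, immediate early genes, heat shock, cholesterol synthesis, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, the RNA interference machinery, enterocyte, goblet and enteroendocrine markers, epithelial junctions, EMT and matrix, TGF-β targets, fibroblast and endothelial markers, and blood cell markers. Each was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 26 lists of a comparison. In every list that passed, the median, the mean and the test had the same sign. The lists share members, and single genes such as BIRC3 and ANGPTL4 stand on more than 1 list.

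The genes named were TNFRSF1A and CTNNB1, the 12 highest and 12 lowest that passed with the same sign on 4 arrays for the mean of both siRNAs, the 10 highest and 10 lowest that passed for the difference with the arrays of the siRNAs not overlapping, and up to 4 members per list with the largest test statistic. Features without a gene symbol were passed over, and a few items that the rule names are not reported here. Where the kept probes of a gene differ in sign, as for TFF3, CLDN7, KLF6, TAPBP, HSP90AA1, AGO1 and MUC17, the gene was left out of the examples of the comparisons, apart from ZNF865.

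Similarity of the siRNAs was measured as Pearson and Spearman correlations across genes, and a reference shared by the arrays of an experiment was simulated in 100 draws. The pipeline was tested on simulated data with 18875 genes, of which 200 were changed. For the mean of both siRNAs it recovered 8% of genes changed by 0.25, 68% of those changed by 0.5 and 96% of those changed by 1 (log2), and 9.09% of calls were false. For siRNA6 it recovered 39% at 0.5 and 85% at 1, with 3.12% of calls false, and for the difference 2% at 0.5 and 50% at 1. Estimates were 0.68 to 0.869 of the simulated change at the median. With so few changed genes the adjusted threshold was stricter than in the real comparisons, so the recovered shares do not give the recovery there.

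The alternatives changed the background correction, the signals (processed or deposited), the scaling between arrays, the filter, the choice of probe, the variance model, the block, the fold threshold, the list test and the arrays included. Alternatives added later are named in the closing section. Control spots, flagged outlier spots and dim probes were left out as described, and no sample or column of the deposited table was left out.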

Results

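Gene expression was measured in SK-CO-1, an established cell line from a human colorectal adenocarcinoma, after RNA interference against β-catenin (CTNNB1), the transcriptional effector of the Wnt pathway, and against the TNF receptor TNFR1 (TNFRSF1A). On each of 4 dual-channel arrays, the Cy5 channel held RNA from cells given 50 nM β-catenin siRNA with 50 nM of a TNFR1 siRNA. The Cy3 channel held RNA from cells given 50 nM β-catenin siRNA with 50 nM control RNA. TNFR1 siRNA5 was used on 2 arrays and TNFR1 siRNA6 on the other two, once each in experiments 1 and 2. Per array, between 48.1 and 54.2% of spots were well above background in Cy3 and between 44.6 and 53.6% in Cy5, 0 spots were saturated, and 18875 genes were tested. Every value is a log2 ratio of Cy5 over Cy3, so a positive value stands for a higher level where a TNFR1 siRNA was added to the β-catenin siRNA. The dyes were not swapped on any array, so a dye effect of a single probe is part of every ratio against 0 and cancels in the difference between the siRNAs. Where arrays share a control RNA, which the labels do not settle, a test of the ratio against 0 also leaves out the control's own spread. The labels number the experiments without stating that the cultures were separate, so the p-values measure only the spread between these samples, and the number of arrays limits the precision.

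The knockdown of the siRNA targets was examined first. TNFRSF1A, which encodes the receptor through which soluble TNF chiefly signals, fell on all 4 arrays, with log2 ratios of -0.78 and -0.78 with siRNA5 and of -1.30 and -1.53 with siRNA6 in experiments 1 and 2. Its mean ratio was -1.10 ± 0.375 (SD, n = 4; limma, adjusted p = 1.74e-08). The transcript remained at 0.581 of the reference level with siRNA5 (adjusted p = 0.000102) and at 0.376 with siRNA6 (adjusted p = 4.98e-08). It was thus 0.63 log2 units higher with siRNA5 than with siRNA6 (adjusted p = 0.00334). CTNNB1, targeted in both channels, had a mean log2 ratio of -0.003 ± 0.202 (SD, n = 4; adjusted p = 0.978), with values of 0.27 and 0.01 for siRNA5 and of -0.09 and -0.20 for siRNA6. A second CTNNB1 probe averaged -0.07 over the same 4 arrays. A ratio within an array cannot show how far β-catenin itself was lowered, since no array held cells without its siRNA. The CTNNB1 probes lie on chromosome 3 at 41281749 to 41281808 and at 41280687 to 41280746. These positions are on hg19 as the array files give them, and the files do not say in which exon or untranslated region the probes lie. From Feature Extraction's processed signals the mean TNFRSF1A ratio was -1.29 with an adjusted p of 0.104, and from the deposited ratios -1.29 with an adjusted p of 0.106.

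**Figure D1:**
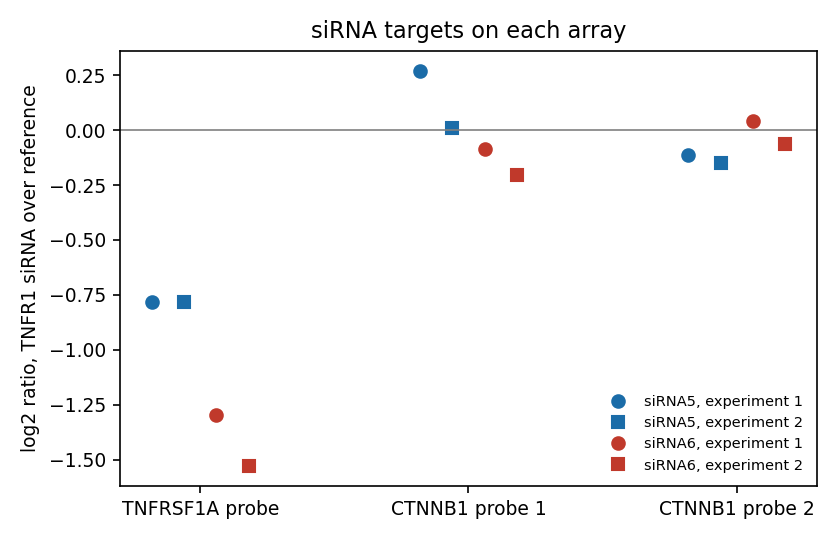
Log2 ratio of Cy5 (β-catenin siRNA plus a TNFR1 siRNA) over Cy3 (β-catenin siRNA) for the probes of the siRNA targets, with 1 point per array and colours for the siRNA. The TNFRSF1A points lie between -1.53 and -0.78, and those of the CTNNB1 probes lie on both sides of 0.

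The mean of both siRNAs asked which transcripts change on average when TNFR1 is lowered on top of β-catenin, and a large response to a single siRNA can pass in it. Transcripts of the translation machinery were among the highest of those that rose. RPS2, a protein of the small ribosomal subunit, rose 2.06-fold (log2 1.04, SE 0.0499, n = 4; adjusted p = 1.74e-08) and was higher on 4 of 4 arrays. RPS18, RPS21 and RPS27 of the small subunit rose with log2 ratios of 0.85, 0.76 and 0.70, and RPL38 and RPL31 of the large subunit with 0.73 and 0.67. The 28S ribosomal RNA gene RNA28SN5 rose with a log2 ratio of 0.76. KRT19, a keratin of simple epithelia, rose 1.81-fold (log2 0.86, SE 0.0563; adjusted p = 4.58e-07). The zinc finger gene ZNF865 read 0.78 on its brightest probe, but its 3 probes differed in sign. Outside this bright group, PEG10, an imprinted gene derived from a retrotransposon, rose 1.63-fold (log2 0.70, SE 0.0656; adjusted p = 1.08e-05), and VAV3 rose 1.58-fold (log2 0.66, SE 0.0498; adjusted p = 1.58e-06). All of these apart from PEG10 and VAV3 had a mean log2 brightness over 17. At that brightness the 31 genes that do not encode ribosomal proteins had medians of 0.44, 0.42, 0.49 and 0.45 on the 4 arrays.

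In the lowest of the transcripts that fell on all 4 arrays, most of the change came from siRNA6. After TNFRSF1A, the lowest mean was that of SPNS2, a transporter of sphingosine-1-phosphate, at -0.83 (SE 0.0559, n = 4; adjusted p = 5.81e-07), with -1.59 for siRNA6 and -0.08 for siRNA5 (adjusted p = 0.607). ANGPTL4, a secreted inhibitor of lipoprotein lipase, averaged -0.80, with -1.45 for siRNA6 and -0.15 for siRNA5 (adjusted p = 0.257). SELENOT, a selenoprotein of the endoplasmic reticulum, averaged -0.79 and passed with either siRNA, at -1.12 for siRNA6 and -0.46 for siRNA5 (adjusted p = 0.0262). The kallikrein serine proteases KLK10 and KLK6 averaged -0.67 and -0.62, and the metalloproteinase inhibitor TIMP2 and the tubulin TUBB6 each averaged -0.57. CYSRT1 averaged -0.67, the antisense transcript SLCO4A1-AS1 -0.63, the mucin-like gene MUCL3 -0.58 and the autophagy gene WDR45 -0.57. In these last 8 genes the siRNA5 values lay between -0.30 and -0.16 and did not pass (adjusted p from 0.052 to 0.239).

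Of the 18875 genes, 4089 passed an adjusted p of 0.05 in limma for the mean of both siRNAs, 2194 higher and 1895 lower. Of these, 3161 had the same sign on all 4 arrays, and the median absolute log2 ratio was 0.21. A change of at least 2-fold was seen in 3 genes, which were RPS2, TNFRSF1A and a transcript without a gene symbol (ENST00000590022, log2 1.14 on average and 1.13 with siRNA5), named after its values were seen. From Feature Extraction's processed signals or from the deposited ratios 0 genes passed in limma, with 4922 and 4906 at an unadjusted p under 0.05, and without the siRNA6 array of experiment 2 the count was 2314. Centring each array on its median in place of loess set the median of all genes to 0.33 and gave 12431 higher and 85 lower, a split that mostly counts this shift. With centring over the tested genes, 4794 were higher and 5363 lower. Directions are thus relative to the loess fit. The fit with 1 mean per siRNA also keeps differences between the siRNAs out of the spread. In an intercept-only model, where such differences enter the spread, 952 genes passed in limma.

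Lists of genes fixed before the data were examined were tested as groups with limma's camera at a preset correlation, and 5 of 26 passed for the mean of both siRNAs, with directions relative to the loess fit. With an estimated correlation 0 lists passed in camera (adjusted p = 0.718 for each of these 5 and 0 unadjusted p under 0.05), and in fry, which tests whether a list's genes move one way on balance, only the ribosomal list passed (adjusted p = 0.0483). Here and below, the estimated version rests on only 2 residual degrees of freedom. In it the BCL2 list went from an unadjusted p of 0.00186 to 0.0996, although its estimated correlation, 0.0157, was near the preset 0.01. For the BCL2 list the lost call therefore does not show that correlation between genes accounts for it. The other lists that passed had estimated correlations far above the preset. These were 0.594 (cell cycle), 0.223 (ribosomal proteins), 0.193 (NF-κB targets) and 0.160 (immediate early). Their p-values at the preset may thus be far too small. How much of their loss comes from correlation and how much from the few degrees of freedom cannot be told. Of 42 ribosomal proteins, 36 rose, 0 fell and 6 did not pass (37 rose adjusted over the list alone), with a median log2 ratio of 0.33 (adjusted p = 2.52e-26), and once the trend with brightness was removed 19 rose and 1 fell with a median of 0.14 (adjusted p = 7.61e-08). The ribosomal protein list had a median log2 brightness of 16.6, and the 123 other genes between 16 and 17 had array medians of 0.16 to 0.17. Over a brightness of 17 the removal of the trend took less than the array medians of the other genes, 0.42 to 0.49. Part of the trend may therefore stay in the median of 0.14 and its p-value. Of 48 cell cycle genes, 20 rose and 0 fell (26 and 0 adjusted over the list alone), with a median of 0.14 (adjusted p = 6.21e-08), and medians of -0.03 for siRNA5 (0.05 and -0.11 on its arrays) and 0.31 for siRNA6. Those that rose included TYMS and RRM2, which make DNA precursors, at 0.54 and 0.29, the transcription factor E2F8 at 0.45 and the mitotic kinase PLK1 at 0.39. Of 37 TNF and NF-κB target genes, 0 rose and 15 fell (0 and 18 adjusted over the list alone), with a median of -0.13 (adjusted p = 9.40e-05). With siRNA5 alone 0 of the 37 passed and the median was -0.01, against -0.16 with siRNA6. Those that fell included the protease PLAU at -0.76 (-0.06 with siRNA5 and -1.455 with siRNA6), the cytokine LIF at -0.47 (0.03 and -0.97) and the chemokines CXCL1 and CXCL3 at -0.38 and -0.31 (-0.23 and -0.18 with siRNA5). Of 30 immediate early genes, which respond to growth factors, 1 rose and 11 fell (1 and 11 adjusted over the list alone), among them the phosphatase DUSP5 at -0.53 and the matricellular gene CCN1 at -0.52, with a list median of -0.08 (adjusted p = 0.000389). With siRNA5 alone 0 of the 30 passed, DUSP5 read -0.0017 and CCN1 -0.08, and the median was -0.01. Of 31 genes of the BCL2 family and caspases, 0 rose and 9 fell (1 and 10 adjusted over the list alone), with a median of -0.08 (adjusted p = 0.00966). The apoptosis inhibitor BIRC2 fell with a log2 ratio of -0.27, BCL2L1 with -0.27 (-0.03 with siRNA5) and the caspase CASP4 with -0.19 (-0.06 with siRNA5). BIRC3 averaged -0.28, but was 0.10 with siRNA5 and -0.66 with siRNA6 (adjusted p of the difference = 0.000529). Under median centring the medians of the NF-κB, immediate early and BCL2 lists were 0.29, 0.31 and 0.39 beside 0.33 for all genes and no longer passed, and the BCL2 call also ended without the siRNA5 array of experiment 1 (adjusted p = 0.0529) and from the processed signals (adjusted p = 0.0942).

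**Figure D2:**
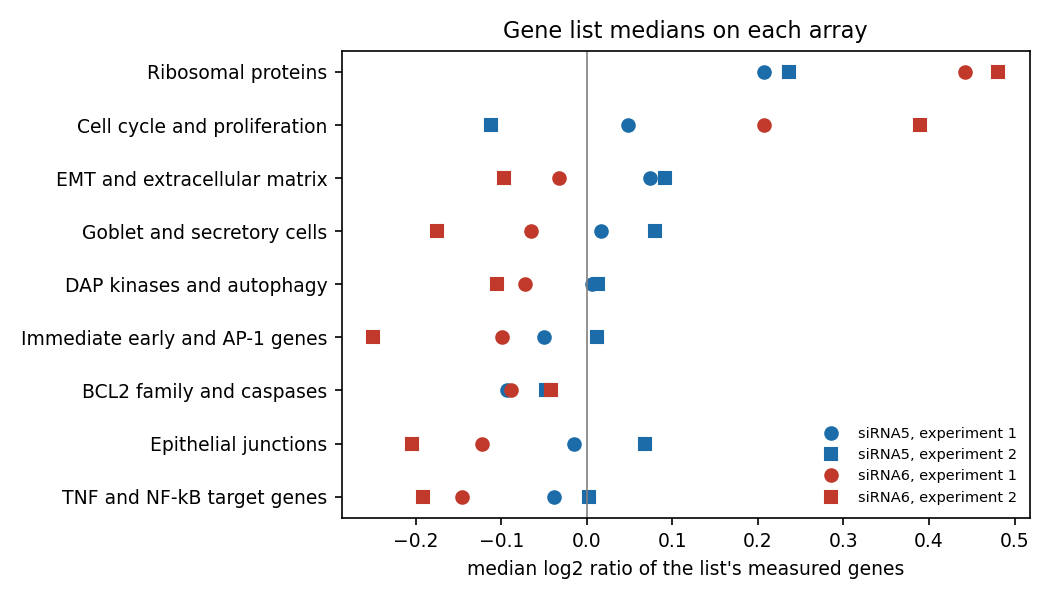
Median log2 ratio of the measured genes of each list that passed in a comparison (y axis), with 1 point per array and colours for the siRNA. Ribosomal protein medians lie above 0 on all 4 arrays, whereas the median of the cell cycle list was 0.31 for siRNA6 and -0.03 for siRNA5.

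No other list passed as a group for the mean of both siRNAs (camera, adjusted p from 0.0883 to 0.997), although single members did. Once the trend with brightness was removed, the epithelial junction list (median -0.09, adjusted p = 0.0142), the goblet list (-0.07, adjusted p = 0.0212) and the heat shock list (0.06, adjusted p = 0.0480) also passed. With an estimated correlation none of these 3 passed before that removal (adjusted p = 0.718 for each). Of 27 genes of the TNFR1 signalling complex, 2 rose and 6 fell (3 and 7 adjusted over the list alone). The kinase MAP3K5 rose with 0.33 and SPATA2 with 0.35, and SHARPIN, a subunit of the linear ubiquitin ligase, fell with -0.33. Of 19 other TNF-family receptors and ligands, 1 rose and 4 fell (4 and 4 adjusted over the list alone), including TNFRSF12A at -0.42 and TNFRSF21 at -0.27. Of 28 Wnt target genes, 1 rose and 5 fell (1 and 5 adjusted over the list alone). The Wnt inhibitor DKK1 rose with 0.29 (0.03 with siRNA5 and 0.54 with siRNA6), and the receptor EPHB3 fell with -0.22. The AP-1 subunit JUN averaged -0.25, but was 0.08 with siRNA5 and -0.58 with siRNA6 (adjusted p of the difference = 0.00328). Of 36 death-associated kinase and autophagy genes, 0 rose and 7 fell (0 and 7 adjusted over the list alone), including ATG16L1 at -0.25 and ATG4A at -0.21. Of 28 p53 target genes, 7 rose and 4 fell (10 and 6 adjusted over the list alone), with MDM2 at 0.28 and PLK3 at -0.36. Of 35 interferon-stimulated genes, 5 rose and 5 fell (6 and 5 adjusted over the list alone), with OAS2 at 0.44 and ISG20 at -0.51. Of 15 antigen presentation genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone), with the immunoproteasome subunit PSMB8 at 0.31 and B2M at -0.25.

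Among stress and metabolism lists, some had members that passed both ways and others in only 1 direction. Of 32 genes of the unfolded protein and integrated stress responses, 4 rose and 6 fell (4 and 6 adjusted over the list alone), with the serine synthesis enzymes PSAT1 and PHGDH at 0.42 and 0.30 and the chaperones PDIA4 and DNAJB11 at -0.38 and -0.33. Of 19 heat shock genes, 5 rose and 0 fell (5 and 0 adjusted over the list alone), including the mitochondrial chaperones HSPD1 and HSPE1 at 0.30 and 0.28. Of 39 nuclear-encoded genes of oxidative phosphorylation, 7 rose and 0 fell (7 and 0 adjusted over the list alone), including UQCRH at 0.30 and ATP5F1A at 0.28. Cholesterol synthesis had 3 higher and 3 lower of 24 (3 and 3 adjusted over the list alone), with DHCR7 at 0.29 and IDI1 at -0.28. Hypoxia and glycolysis had 3 higher and 3 lower of 30 (3 and 3 adjusted over the list alone), with CA9 at 0.27 and P4HA2 at -0.25. Of 13 genes of the RNA interference machinery, 2 rose and 1 fell (2 and 1 adjusted over the list alone), with TNRC6C at 0.36 and AGO4 at -0.20.

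Markers of intestinal and other cell types moved both ways. Of 21 enterocyte genes, 5 rose and 6 fell (5 and 6 adjusted over the list alone), with the fatty acid binding protein FABP1 at 0.38 (-0.11 with siRNA5 and 0.86 with siRNA6) and the peptide hormone gene GUCA2A at -0.42. Of 19 goblet and secretory genes, 2 rose and 4 fell (3 and 4 adjusted over the list alone), with the trefoil peptide TFF2 at -0.49 and SPINK4 at -0.42. Of 26 epithelial junction genes, 4 rose and 6 fell (5 and 6 adjusted over the list alone), with E-cadherin (CDH1) at -0.49 and the junctional adhesion molecule F11R at -0.36. Of 20 EMT and matrix genes, 0 rose and 4 fell (0 and 4 adjusted over the list alone), including the laminin chain LAMB3 at -0.40 and the protease MMP14 at -0.33. Of 20 TGF-β target genes, 4 rose and 3 fell (4 and 3 adjusted over the list alone), with ID3 at 0.42. Of 6 enteroendocrine genes 1 rose, SCG5 at 0.22 (1 adjusted over the list alone). Of 6 fibroblast and endothelial markers 1 rose (1 adjusted over the list alone). This was TEK, for which Cy3 was not well above background on any array and Cy5 on only 2. Its mean Cy5 signal over the 4 arrays was 1.08-fold above the background floor of Cy3. This is not a firm lower bound, since it includes arrays with both channels near background. Of 10 blood cell markers 0 passed (0 adjusted over the list alone), and the macrophage marker CD68 averaged -0.07 (adjusted p = 0.316), with 0.15 for siRNA5 and -0.29 for siRNA6, of which the latter passed (adjusted p = 0.00775).

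The siRNAs were then compared with the reference singly. With siRNA6, F3 (tissue factor) and SPNS2 fell, each about 3-fold (log2 -1.58 and -1.59, SE 0.0739 and 0.0791, n = 2; adjusted p = 3.35e-08 for both), and both arrays showed the direction. With siRNA5 the highest value among the named genes with a symbol was that of KRT19, which rose 1.96-fold (log2 0.97; adjusted p = 2.93e-05), followed by RNA28SN5 at 0.89 and RPS2 at 0.82. With siRNA6, RPS2 rose with 1.27 and KRT19 with 0.75. In limma, 4548 genes passed with siRNA6, 2373 higher and 2175 lower, and 26 of them changed at least 2-fold, 3 higher and 23 lower. With siRNA5, 559 genes passed, 376 higher and 183 lower, and 1, the transcript without a symbol, changed at least 2-fold. Once the trend with brightness was removed, the siRNA5 split was 158 higher and 146 lower. From the processed signals or the deposited ratios 0 genes passed with either siRNA, with 2639 and 2660 for siRNA5 and 5253 and 5283 for siRNA6 at an unadjusted p under 0.05. The siRNA5 count was 47 without background correction, 846 with experiment as a block, 134 without its array of experiment 1, 864 without that of experiment 2 and 1193 without either siRNA6 array, while the siRNA6 count was 1557 without its array of experiment 2. Under median centring, which moved the median of all genes above 0, the splits were 11032 higher and 38 lower for siRNA5, and 8278 higher and 113 lower for siRNA6. With centring over the tested genes they were 2759 higher and 3946 lower for siRNA5, and 3565 higher and 3081 lower for siRNA6. The order of the counts is thus relative to the loess fit.

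**Figure D3:**
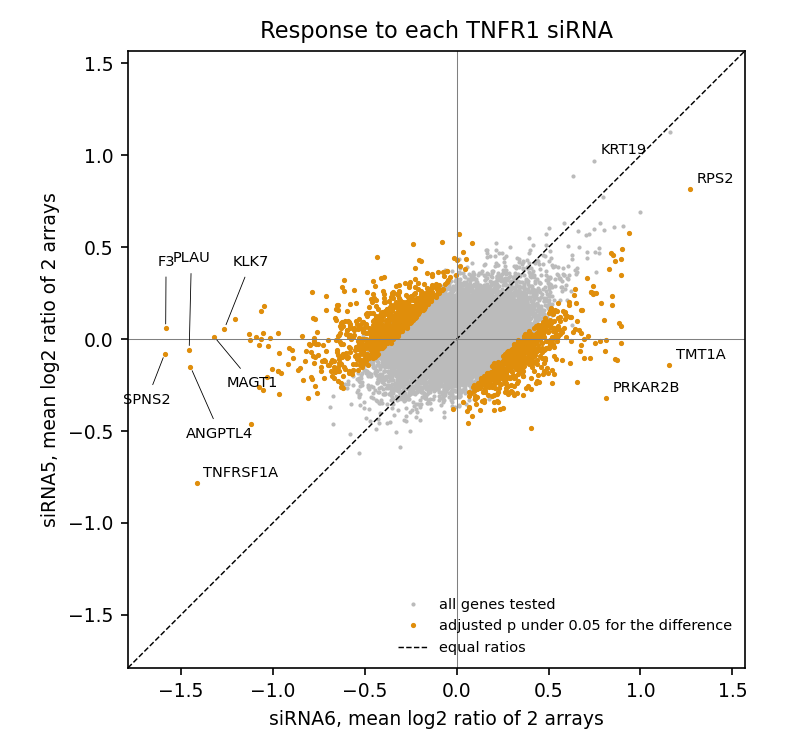
Mean log2 ratio of each gene with siRNA6 (x axis) and siRNA5 (y axis), each from 2 arrays, with genes that passed for the difference in orange, equal ratios as a dashed line and labels on 11 genes. F3 and SPNS2 lie near -1.6 with siRNA6 and near 0 with siRNA5, and TNFRSF1A is low with both, at -0.78 and -1.41.

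With siRNA5, 1 of 26 lists passed. Of 42 ribosomal proteins 15 rose and 0 fell (26 and 0 adjusted over the list alone), with a median of 0.23 (adjusted p = 1.90e-14, and adjusted p = 0.854 with an estimated correlation). That median was 0.01 from the processed signals (adjusted p = 0.552) and 0.03 once the trend with brightness was removed (adjusted p = 0.396). With siRNA6, 8 lists passed, with directions again relative to the loess fit (adjusted p = 0.686 for each with an estimated correlation). Ribosomal proteins had 40 higher and 0 lower (40 and 0 adjusted over the list alone) with a median of 0.44 (adjusted p = 3.17e-26), or 27 higher with a median of 0.25 once the trend with brightness was removed (adjusted p = 1.21e-11), and cell cycle genes 37 higher and 0 lower (44 and 0 adjusted over the list alone) with a median of 0.31 (adjusted p = 5.61e-17). Part of the trend may stay in the ribosomal median of 0.25, as for the mean of both siRNAs. TNF and NF-κB target genes had 1 higher and 17 lower (1 and 18 adjusted over the list alone) with a median of -0.16 (adjusted p = 1.92e-05), and LIF fell with -0.97. Immediate early genes had 1 higher and 12 lower (1 and 13 adjusted over the list alone) with a median of -0.16 (adjusted p = 0.000461), and DUSP5 fell with -1.07. Epithelial junction genes had 1 higher and 10 lower (1 and 13 adjusted over the list alone) with a median of -0.17 (adjusted p = 0.000588), and CDH1 fell with -0.67. Goblet and secretory genes had 1 higher and 7 lower (1 and 7 adjusted over the list alone) with a median of -0.15 (adjusted p = 0.0122), and TFF2 fell with -0.89. Autophagy genes had 0 higher and 10 lower (0 and 11 adjusted over the list alone; adjusted p = 0.0192), and EMT and matrix genes 0 higher and 6 lower (0 and 6 adjusted over the list alone; adjusted p = 0.0368). Under median centring, which set the median of all genes to 0.28 for siRNA6, these 6 lower lists had medians of 0.20 (NF-κB), 0.21 (immediate early), 0.35 (junctions), 0.29 (goblet), 0.22 (autophagy) and 0.13 (EMT), and of these the NF-κB list alone still passed (adjusted p = 0.0483). Without the siRNA6 array of experiment 2 the autophagy and EMT lists no longer passed (adjusted p = 0.30 and 0.0522), and neither passed from the processed signals (adjusted p = 0.0657 and 0.238).

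Effects shared between the siRNAs were compared through overlap and correlation. RPS2, KRT19, PEG10, VAV3 and SELENOT were among the 294 genes that passed with each siRNA in the same direction, 204 higher and 90 lower, where independent lists would share 47.3 and 21.1. Of these 294, 281 did not pass for the difference between the siRNAs, while RPS2, VAV3 and SELENOT did (limma, adjusted p = 0.0156, 0.0143 and 0.0133). Not passing does not show equal effects. On simulated data 2% of differences of 0.5 were recovered, but only 200 genes were changed there, which makes the adjusted threshold stricter. In the real data the genes that passed for the difference had a median absolute value of 0.44, so the simulated share does not carry over. Another 25 genes passed with each siRNA in opposite directions. The 294 became 43 without background correction, 17 with a normexp offset of 16, 162 once the trend with brightness was removed, 7162 under median centring and 0 from the processed signals or the deposited ratios, and the 25 became 0, 0, 12, 48 and 0. Arrays of the same experiment may share their reference RNA. In 100 simulations of a shared reference without siRNA effects, 0 genes passed with both siRNAs, and 183.3 had an unadjusted p under 0.05 with each siRNA in the same direction, against 1473 observed. Neither the simulations nor the independent lists held a dye bias of single probes or a trend with brightness. With no dyes swapped, both would be shared by the arrays. The overlap and the correlations below therefore cannot tell shared effects of the siRNAs from such biases. Across genes, which are not independent replicates, Pearson's r was 0.756 (rho 0.684) between the siRNA6 arrays and 0.442 (rho 0.411) between the siRNA5 arrays. Between different siRNAs in different experiments r was 0.284 and 0.251 (rho 0.251 and 0.212), and in the same experiment 0.224 and 0.214 (rho 0.198 and 0.181). The mean r of different siRNAs in different experiments, 0.268 after loess, was 0.612 under median centring and 0.197 from the processed signals. In the simulations r averaged 0.501 in the same experiment, -0.0009 in different experiments and 0.5004 between the siRNA means, against mean values of 0.219, 0.268 and 0.307 observed. The covariance of the siRNA means was 0.00803, against 0.00274 simulated, and that within an experiment 0.00711 against 0.00549. Between different siRNAs it was 0.0111 and 0.00681 in different experiments and 0.00734 and 0.00688 in the same experiment. A reference shared within an experiment would raise only the latter.

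The difference between the siRNAs asked which responses depend on the siRNA used, a contrast in which dye effects cancel. F3 read 0.06 with siRNA5 and -1.58 with siRNA6, a difference of 1.64 (SE 0.104, n = 2 per siRNA; adjusted p = 2.76e-06). SPNS2 differed by 1.51, PLAU (urokinase) by 1.40, ANGPTL4 by 1.30 and the protease KLK7 by 1.32, each with a siRNA5 value between -0.15 and 0.06. MAGT1, a magnesium transporter, differed by 1.33, FAXDC2 by 1.32, DENND2C by 1.23, the paraoxonase PON2 by 1.22 and the integrin ITGB8 by 1.16. Higher with siRNA6 were TMT1A, which read -0.14 and 1.16 (difference -1.30, SE 0.0965; adjusted p = 7.71e-06), and PRKAR2B, a regulatory subunit of protein kinase A, which passed in opposite directions at -0.32 and 0.81. FABP1 and FABP5, which bind fatty acids, differed by -0.97 and -0.79, and the intestinal homeobox gene ISX by -0.87. The aldo-keto reductases AKR1C8 and AKR1C3 differed by -0.83 and -0.80, the gastric mucin MUC6 by -0.81, WFDC21P by -0.91 and GAS6-AS1 by -0.89. In limma 1356 genes passed for the difference, 774 higher with siRNA5 and 582 higher with siRNA6, and 20 differed at least 2-fold, 18 and 2 in that order. The split was 112 and 22 under median centring, 96 and 35 with a normexp offset of 16, and 86 and 33 with centring over the tested genes. The count was 603 without the siRNA6 array of experiment 2 and 134 under median centring, and from the processed signals or the deposited ratios it was 0, with 3238 and 3227 at an unadjusted p under 0.05.

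**Figure D4:**
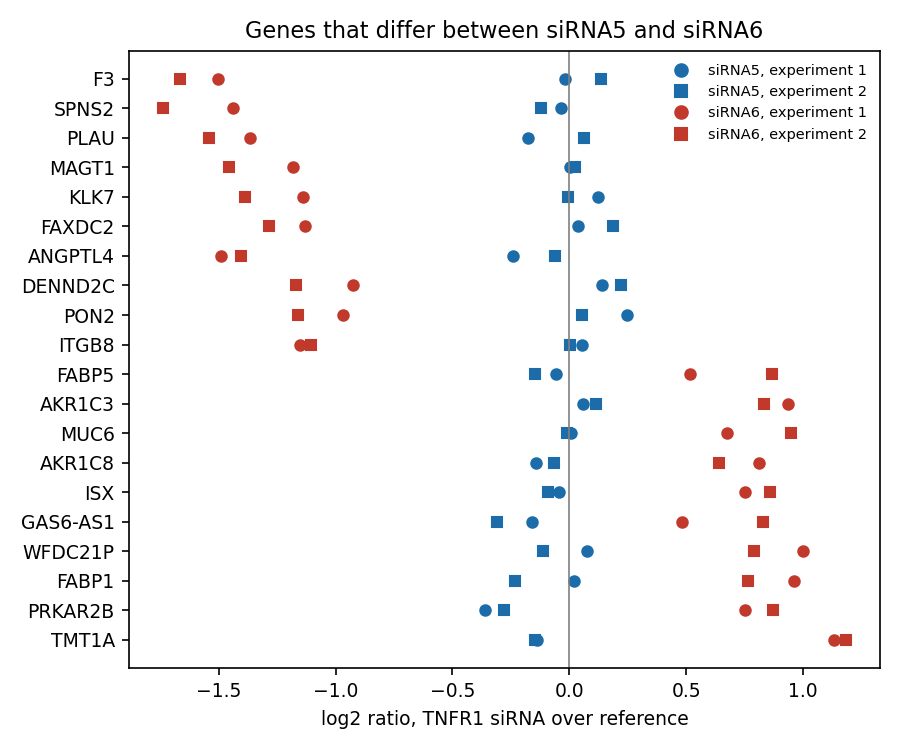
Log2 ratio on each array (points, coloured by siRNA) of the genes named for the difference between siRNA5 and siRNA6. F3 reads 0.06 on average with siRNA5 and -1.58 with siRNA6, and TMT1A -0.14 and 1.16.

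As groups, 7 of the 26 lists differed between the siRNAs (adjusted p = 0.660 for each with an estimated correlation). Cell cycle genes were higher with siRNA6, with a median difference of -0.34 and 0 genes higher with siRNA5 and 17 with siRNA6 (0 and 39 adjusted over the list alone; adjusted p = 4.55e-20). PCNA, the sliding clamp of DNA replication, differed by -0.55 and TYMS by -0.61. Ribosomal proteins differed by -0.23 (0 and 5 genes; 0 and 7 adjusted over the list alone; adjusted p = 4.04e-12), with RPS2 at -0.45 and RPL14 at -0.45. Epithelial junction genes were lower with siRNA6, with a median difference of 0.24 (7 and 0 genes; 12 and 0 adjusted over the list alone; adjusted p = 1.16e-06), and p120-catenin (CTNND1) differed by 0.67. TNF and NF-κB target genes differed by 0.22 (7 and 0 genes; 18 and 2 adjusted over the list alone; adjusted p = 0.00038), with LIF at 1.00 and BIRC3 at 0.76. Goblet and secretory genes differed by 0.18 (5 and 0 genes; 5 and 0 adjusted over the list alone; adjusted p = 0.00077), with TFF2 at 0.79 and the mucin MUC1 at 0.66. EMT and matrix genes differed by 0.09 (5 and 0 genes; 8 and 0 adjusted over the list alone; adjusted p = 0.00503), with the laminin chains LAMA3 and LAMB3 at 0.74 and 0.56. Immediate early genes differed by 0.13 (7 and 1 genes; 11 and 2 adjusted over the list alone; adjusted p = 0.00551), with DUSP5 at 1.06 and JUN at 0.66, and this call ended with the processed signals (adjusted p = 0.0587) and the deposited ratios (adjusted p = 0.0520). No other list passed for the difference (adjusted p from 0.0563 to 0.930).

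**Figure D5:**
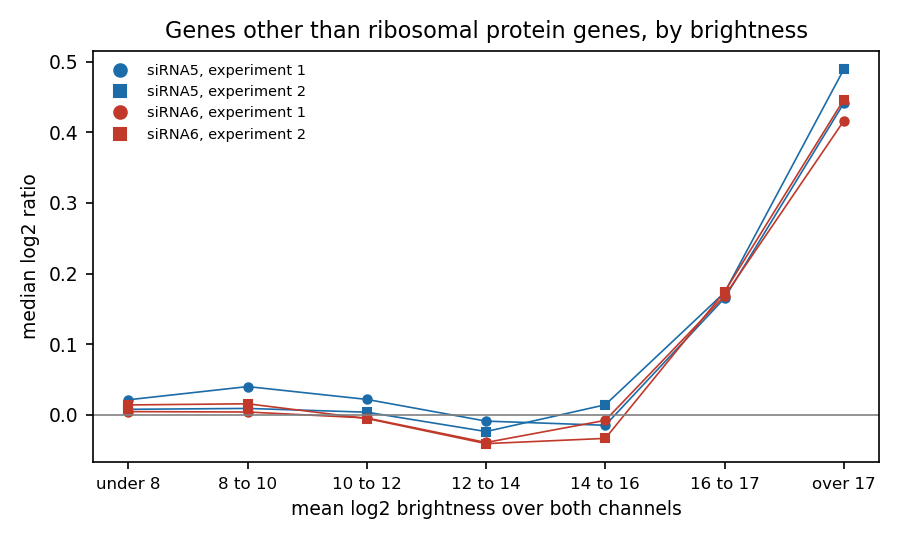
Median log2 ratio of genes other than ribosomal protein genes (y axis) by mean log2 brightness (x axis), with 1 line per array. All 4 arrays rise together in the brightest genes, with medians of 0.42 to 0.49 over a brightness of 17.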

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

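The results in this part differ between siRNA5 and siRNA6 in limma's test of the difference itself, and values are siRNA5 minus siRNA6 on the log2 scale. The tests of noise and of proportion to the knockdown were set before their results were seen, and the tests of brightness, dye bias, probe GC content and choices of sign only afterwards.

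In all, 1356 genes differed between the siRNAs, against 445 without background correction, 131 with a normexp offset of 16 and 134 under median centring. From the processed signals or the deposited ratios 0 genes differed. The list medians that differed were those of TNF and NF-κB targets (0.22), cell cycle genes (-0.34), immediate early genes (0.13), ribosomal proteins (-0.23), goblet and secretory genes (0.18), epithelial junctions (0.24) and EMT and matrix genes (0.094). These calls were made in camera at a preset correlation, and with an estimated correlation each had an adjusted p of 0.660 and in fry 0 lists passed. The immediate early call also ended with the processed signals (adjusted p = 0.0587) and the deposited ratios (adjusted p = 0.0520). TNFRSF1A differed by 0.63, with more transcript left with siRNA5. Among genes named for the mean of both siRNAs, RPS2 (-0.45) and VAV3 (-0.46) rose more with siRNA6 (adjusted p = 0.0156 and 0.0143). SPNS2 (1.51), ANGPTL4 (1.30), MUCL3 (0.84), KLK6 (0.83), KLK10 (0.82), WDR45 (0.80), TUBB6 (0.80), CYSRT1 (0.78), TIMP2 (0.77), SLCO4A1-AS1 (0.67) and SELENOT (0.66) were lower with siRNA6 (adjusted p from 7.71e-06 to 0.0133).

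After loess, more genes changed with siRNA6, 4548, than with siRNA5, 559. This order depends on the scaling, since median centring gave 8391 with siRNA6 and 11070 with siRNA5, and centring over the tested genes 6646 and 6705, whereas from the processed signals 5253 and 2639 genes had an unadjusted p under 0.05. The gap in counts was also narrower without the siRNA6 array of experiment 2, whose log2 ratios spread most widely over genes (SD 0.234). What follows was tested on the ratios after loess. Noisier siRNA5 arrays would need a wider spread between them, but the SD of the difference between arrays was 0.163 for siRNA5 and 0.154 for siRNA6, a ratio of 1.053. The siRNA5 arrays were thus hardly noisier. The tests pooled the spread over both siRNAs, so noise in 1 siRNA would widen both tests alike, and this ratio cannot weigh on the gap in counts. After the trend with probe GC content was removed, 4546 genes passed with siRNA6 and 495 with siRNA5, and 1298 still differed. This argues against probe GC content as the cause. A response in proportion to the TNFRSF1A knockdown would put siRNA5 responses at 0.513 to 0.604 of those to siRNA6, whereas genes chosen on 1 siRNA6 array had ratios of 0.197 (95% interval 0.161 to 0.235, 344 genes) and 0.308 (0.276 to 0.341, 772 genes) on the arrays of the other experiment, a mean of 0.2527 that argues against proportion as the whole cause (0.397 and 0.425 for genes that rose, 0.0562 and 0.211 for those that fell). Each ratio rests on 1 array per siRNA, and the intervals cover the choice of genes and not the spread between arrays. The choice of scaling stays open as a part of the pattern. A response that starts only below some level of TNFR1 may remain, as may effects of either siRNA on transcripts other than its target. The sequences of the siRNAs are not given and only 2 were used, so neither was tested.

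Ribosomal protein transcripts read higher with siRNA5 by a median of 0.23 and with siRNA6 by 0.44. For siRNA5 a trend of the ratio with brightness that loess left is a candidate explanation, since the median was 0.03222 after the running median of other genes of like brightness was subtracted, and 10000 random lists matched for brightness gave a central 95% range of 0.143 to 0.248 around 0.195. A dye bias of these probes cannot be told apart from a response to siRNA5, since 33 of 42 members were above 0 on all 4 arrays and no array had swapped dyes. The part by which siRNA6 exceeded siRNA5 was -0.2343 as measured, where a dye bias common to the arrays cancels, -0.2102 after the brightness trend was removed and -0.2398 after the GC trend was removed, which argues against each of these as its whole cause. A response of ribosomal protein transcripts to siRNA6 that siRNA5 does not give in the same measure may therefore be followed up, though whether it comes from TNFR1 was not tested.

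The mean of both siRNAs rests on 4 arrays, which allow 8 choices of sign for the array ratios. The real choice gave 4089 genes and the highest of the others, which sets siRNA5 against siRNA6, gave 1356. It was the 1 choice of the 8 with so many, but 8 choices are too few for a share under 0.05. A dye bias or a brightness trend shared by the arrays would also count in full only with the real choice. The counts therefore cannot tell effects of the siRNAs from such biases.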

How the results depend on the processing

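Of 5084 values of single named genes under the alternatives, 3819 stayed on their side of the threshold without a counted change of sign. Another 1146 kept direction but no longer passed, 63 newly passed and 56 changed sign. Here and below, a change of sign is counted only where the main or the alternative value passed. The 3819 can therefore hold changes of sign between values that both did not pass. Of 425 list medians, 388 stayed, 24 no longer passed and 13 changed sign, of 28 correlations between arrays of 1 siRNA 18 stayed and 10 moved, and of 66 counts of lists for siRNA5, siRNA6 and the difference 50 stayed and 16 moved. The intercept-only fit with experiment as a random block, the crossed block, the removal of the brightness trend and of the GC trend, centring of the deposited ratios, centring over the tested genes and processed signals of bright probes were chosen after seeing the data. The planned random block with 1 mean per siRNA could not be fitted, and leaving out saturated spots was not run because there were 0. Between 44.6 and 54.2% of spots per channel were well above background, which limits what dim genes can show. Unless stated, the cause of a change was not tested.

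Without background correction 47 genes passed with siRNA5 and 445 for the difference, and with a normexp offset of 16 it was 2589 for the mean of both, 17 with siRNA5, 2924 with siRNA6 and 131 for the difference. From the processed signals 0 genes passed in limma for the mean of both, with siRNA5, with siRNA6 and for the difference (4922, 2639, 5253 and 3238 at an unadjusted p under 0.05). From the deposited ratios it was also 0 in each (4906, 2660, 5283 and 3227), and 0 once they were centred (4896, 2626, 5266 and 3245). TNFRSF1A read -1.29 from the processed signals (adjusted p = 0.104), -1.29 from the deposited ratios (adjusted p = 0.106) and -1.29 after centring (adjusted p = 0.108). From processed signals of the 15093 genes bright in both channels, with a variance trend, 1 gene passed for the mean of both, 0 with siRNA5, 2135 with siRNA6 and 0 for the difference (5187, 2727, 5664 and 3683 at an unadjusted p under 0.05), TNFRSF1A was -1.29 (adjusted p = 0.0614) and 9 lists passed. The mean over probes gave 328 genes with siRNA5, and a robust variance trend 354. Requiring at least 2-fold left 3, 1, 26 and 20 genes for the mean of both, siRNA5, siRNA6 and the difference, by its construction. The intercept-only model, in which differences between siRNAs enter the spread, gave 952 genes for the mean of both, and 6472 with experiment as a random block, whose correlation was estimated at -0.597. With experiment as a fixed block 846 genes passed with siRNA5, and 4028, 4466 and 1537 for the mean of both, siRNA6 and the difference. Crossed pairs gave 1313 genes with siRNA5 and 2215 for the difference. Removing the brightness trend gave 304 genes with siRNA5 and 8 lists for the mean of both, and no filter on dim probes gave 8 lists. With an estimated correlation 0 lists passed in camera (0 at an unadjusted p under 0.05), and 1 passed in fry (4 at an unadjusted p under 0.05). Leaving out 1 array at a time, with a lone array assumed to vary like the others, gave 2314 to 3963 genes for the mean of both, 134 to 1193 with siRNA5, 1557 to 5344 with siRNA6 and 603 to 1489 for the difference, TNFRSF1A between -1.16 and -1.04 and 4 to 6 lists.

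Median centring in place of loess, which set the median of all genes to 0.33 for the mean of both and 0.28 for siRNA6, gave 12516 genes for the mean of both, 11070 with siRNA5, 8391 with siRNA6 and 134 for the difference, 9 lists and a correlation between siRNAs of 0.612. List medians that were negative read, for the mean of both, 0.29 (NF-κB targets), 0.39 (BCL2 family) and 0.31 (immediate early), and for siRNA6 0.20 (NF-κB targets), 0.22 (autophagy), 0.21 (immediate early), 0.29 (goblet), 0.35 (junctions) and 0.13 (EMT). Genes that were negative for the mean of both read positive, namely CTNNB1 0.47, KLK6 0.0024, TUBB6 0.0066, SHARPIN 0.21, BIRC3 0.18, TNFRSF12A 0.20, TNFRSF21 0.38, LTBR 0.31, TNFSF15 0.17, LIF 0.069, CXCL1 0.26, CXCL3 0.17, PRDM1 0.11, JUN 0.21, EPHB3 0.17, BIRC2 0.20, BCL2L1 0.16, CASP4 0.39, ATG16L1 0.24, ATG4A 0.26, BNIP3L 0.37, GABARAPL2 0.19, ISG20 0.14, B2M 0.39, HLA-F 0.39, PLK3 0.10, TP53I3 0.26, DNAJB11 0.18, PDIA4 0.20, KLF6 0.076, KLF2 0.19, IDI1 0.19, P4HA2 0.25, AGO4 0.029, GUCA2A 0.091, CEACAM6 0.13, TFF2 0.22, SPINK4 0.25, CDH1 0.13, CLDN7 0.20, F11R 0.27, LAMB3 0.25, MMP14 0.081, ITGB6 0.21 and CD68 0.39, where the kept probes of KLF6 and CLDN7 differ in sign. Without the filter on dim probes the EMT list read 0.0082 with siRNA6. Centring over the tested genes, which set their median near 0, gave 10157 genes for the mean of both, 6705 with siRNA5 and 119 for the difference, 9 lists and a correlation of 0.612. Under it the BCL2 list read 0.062 for the mean of both, and the goblet and junction lists 0.0058 and 0.066 for siRNA6. Named genes that changed sign for the mean of both read TNFRSF21 0.050, CASP4 0.062, BNIP3L 0.042, B2M 0.060, HLA-F 0.066, MEP1A -0.0067, PAX4 -0.27, GCG -0.25, LUM -0.24 and CD3E -0.23. COL1A1 had a fitted value of -0.28 there, from which no change is read, since its Cy3 signal was not well above background on any array.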

Other observations

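The gene families and genes in this part were chosen after values had been seen, and 15 families were examined with camera, whose p-values partly restate what had been seen. Kallikreins, secreted serine proteases, and aldo-keto reductases were picked because members stood among the genes furthest apart between the siRNAs or lowest for their mean, so only their values are given. Of 10 kallikreins measured, 6 fell and 0 rose with siRNA6, with a median log2 ratio of -0.72, and the median stayed negative under 8 scalings (-0.32 under median centring, beside 0.28 for all genes). KLK7 read -1.26, KLK8 and KLK10 -1.07, KLK6 -1.03, KLK11 -0.76 and KLK12 -0.67 with siRNA6. With siRNA5 their median was -0.03, and the median difference between the siRNAs was 0.62. Of 8 aldo-keto reductases measured, which reduce steroids and other carbonyl compounds, 6 rose and 0 fell with siRNA6, with a median of 0.50, and the median stayed positive under the same 8 scalings. AKR1C3 rose with 0.89, AKR1C4 with 0.75, AKR1C8 with 0.73, AKR1C1 with 0.63, AKR1B10 with 0.36 and AKR1B1 with 0.30. With siRNA5 their median was 0.04, and the median difference was -0.40. Members of these families resemble each other, so their probes are not independent measurements.

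Of the other 13 families, 6 passed with siRNA6 in camera at a preset correlation (adjusted p = 0.526 to 0.541 with an estimated correlation). Of 7 genes with UGT symbols, 5 rose, with a median of 0.25 (adjusted p = 0.00648). They hold UDP-glucuronosyltransferases, which conjugate steroids and drugs, and also UGT8, which is not of that class and did not pass. Of the 6 MCM helicase genes of DNA replication 5 rose, with a median of 0.33 (adjusted p = 0.00159). All 6 also stand on the cell cycle list, so this restates part of that list's result. Of 80 mitochondrial ribosomal proteins 18 rose and 2 fell, with a median of 0.10 (adjusted p = 0.00159). Of 75 histone genes 23 rose and 3 fell, with a median of 0.04 (adjusted p = 0.00491). Keratins had 2 higher and 15 lower of 38, with a median of -0.16 (adjusted p = 0.00142) that turned to 0.15 under median centring, beside 0.28 for all genes, and no longer passed there or with centring over the tested genes (adjusted p = 0.174 and 0.110). Of 12 serpins 1 rose and 4 fell, with a median of -0.14 (adjusted p = 0.0448), but this call ended under 6 of the 8 other scalings, namely no background correction (adjusted p = 0.0609), a normexp offset of 16 (0.0554), the processed signals (0.159), the deposited ratios (0.0740), centring over the tested genes (0.172) and median centring (0.186), which turned the median to 0.19. With siRNA5, 1 of the 15 families passed, the proteasome at -0.08 (adjusted p = 0.00643, and 0.92 with an estimated correlation), which no longer passed at -0.06 once the brightness trend was removed (adjusted p = 0.101) and turned to 0.54 under median centring, beside 0.37 for all genes, and to 0.16 with centring over the tested genes. Mucins, solute carriers, zinc finger proteins, metallothioneins, HLA class II and mitochondrial complex I did not pass with either siRNA or for their mean after loess. Complex I passed with siRNA6 once the brightness trend was removed (median 0.07, adjusted p = 0.0131, and 0.578 with an estimated correlation before the removal), and under both centrings complex I and HLA class II passed with each siRNA and for their mean (for the mean under median centring, medians of 0.57 and 0.04 beside 0.33 for all genes, adjusted p = 4.42e-09 and 0.0117).

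Some genes passed with each siRNA in opposite directions, relative to the loess fit. Of these 25 genes, 22 carry a current symbol, and without background correction 0 genes passed in opposite directions. RBMS1, an RNA-binding protein, read 0.32 with siRNA5 and -0.61 with siRNA6 (adjusted p of the difference = 0.000208), the adaptor SHC4 0.28 and -0.62 (0.000161) and the epithelial cytokine IL17C 0.32 and -0.45 (0.0012). The cell cycle inhibitor CDKN1C read 0.34 and -0.40 (0.00108) and the GTPase RHOB 0.30 and -0.32 (0.00227). The histone variant H2AX read -0.38 and 0.21 (0.00354), and the hedgehog ligand IHH -0.34 and 0.22 (0.00364). Each of these had 1 sign on both siRNA5 arrays and the other on both siRNA6 arrays. The bright transcripts TFF1 (0.52 and -0.24) and LAMA3 (0.33 and -0.41) lie where the array medians are themselves above 0.

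After the brightness trend was removed, an alternative added after seeing the data, several genes outside the ribosome stood among the highest for the mean of both siRNAs. PEG10 rose with 0.71, VAV3 with 0.68, MAOA, which degrades monoamines, with 0.61 and TYMS with 0.56. Only genes higher on 4 of 4 arrays were ranked here, so that trait was fixed by the choice. Before the removal TYMS read 0.23 with siRNA5, which did not pass (limma, adjusted p = 0.164), and 0.85 with siRNA6. PEG10, VAV3 and MAOA passed with each siRNA. RPS2 went from 1.04 to 0.74 and KRT19 from 0.86 to 0.56. Both have a brightness over 17, where the removal took the same amount from each named gene. The other genes there had larger array medians, 0.42 to 0.49. Part of the trend thus stays in the values of RPS2 and KRT19, and may stay in the ribosomal medians and p-values that follow. The median of the ribosomal list fell from 0.33 to 0.14 for the mean of both (19 higher and 1 lower; adjusted p = 7.61e-08), from 0.44 to 0.25 for siRNA6 (adjusted p = 1.21e-11) and from 0.23 to 0.03 for siRNA5 (adjusted p = 0.396). These are camera tests at a preset correlation, and before the trend was removed the list passed in none of these with an estimated correlation (adjusted p = 0.718, 0.686 and 0.854).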
